A study of Mus musculus with 2 samples.

How the data were processed

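Single cells from whole aortas of female wild-type C57/BL6 mice aged 12 weeks on chow were measured with droplet libraries (10x v2), 1 library for each of 2 aortas. Per the labels the aortas were digested with enzymes for 1 hour at 37 °C, perivascular fat was removed, red cells were lysed, and no selection for a cell type is described. Cells on a Western diet and libraries of low depth, which the labels mention, were not used here. The deposited values are counts of UMIs per gene and cell (16971 genes, 5451 cells), made with Cell Ranger 2.1 per the submitters' processing notes. The genome build and annotation are not stated. The cells had been filtered before deposition: from the values, every cell has at most 14968 UMIs, 3998 genes and 24.9% mitochondrial UMIs. The authors' names for 10 populations were taken as given, as text per cell. Cells were assigned to library 1 or 2 by the number at the end of their barcode. Which of these is the aorta labelled replicate 1 and which replicate 3 is not stated, so the libraries carry these numbers only. The analysis has 1 group of 2 libraries.

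UMIs were summed for each population of each library with at least 10 cells. Genes were kept by filterByExpr (10488 tested) and normalized by TMM, and 1 quasi-likelihood fit with population and library as terms (residual degrees of freedom 9, common dispersion 0.013) was made with edgeR 4.0.16 in R 4.3.3. Each pair of endothelial populations was compared, and each of 4 classes (endothelial, smooth muscle, fibroblast, immune) as the mean of its populations with the mean of the other 3. P-values were adjusted by Benjamini-Hochberg over all genes, and again over each list alone. Gene lists were tested with camera of limma 3.58.1 at a correlation of 0.01 and with an estimated correlation, and p-values were adjusted over the 28 lists with enough genes in the 3 comparisons together. Folds against a population without a UMI are given as lower bounds against 3 counts over the population, and with 1 to 3 UMIs as ratios with a counting interval. Library folds are log2 ratios of CPM with a prior count of 2, and folds with equal weight of cells are log2 ratios after adding 5 CPM.

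The comparisons, gene lists, alternatives and the rule for naming genes were fixed before the data were examined, with exceptions. These were the comparisons of fibroblast and of monocyte populations, and the alternative without endothelial cells rich in pericyte or haemoglobin UMIs. The rule takes the 10 genes with the largest fold in each direction among called genes with at least 50 UMIs and the same direction in each library, up to 4 members of each list with the largest absolute fold, and 15 fixed genes. Chosen after their values were seen were Apoe, C1qa, Cd74, H2-Ab1, Klf2, Lpl, Meox2, Plvap and Rgs5 between EC 1 and EC 2, Itga9 between EC 1 and EC 3, and Hbb-bs between EC 2 and EC 3. So were Bst2 in the endothelial class, Fos in the immune class, the genes counted cell by cell, and Gkn3, Cytl1 and Clu in the figure of endothelial genes. The levels of C1qa and Mrc1 in Mono 1, Mono 2 and Macro were also chosen outside the rule.

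The alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, no library term, each library alone, doublets left out (Scrublet in scanpy 1.11.5, 58 cells of library 1 and 40 of library 2), cells thinned to 1300 UMIs, equal weight of cells, only the populations compared, at least 25 cells, the 10% of cells with fewest and the 10% with most UMIs left out, and UMIs split at random into 2 equal parts, with clusters made on 1 part and compared on the other. In the split only the endothelial cells were clustered, and all other cells kept the authors' names. For lists fry was also run. Own clusters used Leiden (leidenalg 0.10.2, resolution 0.8, 20 components). Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On data simulated from the fitted means, genes changed 2-fold were recovered in 65%, 47% and 63% of cases for EC 1 against EC 2, EC 1 against EC 3 and EC 2 against EC 3, and genes changed 4-fold in 100% in each. Of 9951, 9929 and 9977 unchanged genes 15, 15 and 9 were called. Of 20 random lists of unchanged genes per comparison, 0, 3 and 0 had a camera p under 0.05 before adjustment. The changed genes were drawn from those with at least 50 UMIs in the populations compared. Counts were drawn independently for each gene, and clustering on the same counts was not simulated. The simulation thus cannot show how often calls are false for correlated lists, or how many genes with fewer UMIs are recovered.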

Results

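The data are an atlas of gene expression in the normal mouse aorta, made to describe its cells and to ask how its endothelial populations differ. RNA was measured by droplet single-cell sequencing in dissociated whole aortas of wild-type female C57/BL6 mice aged 12 weeks on a chow diet. The deposited table counts UMIs (unique molecular identifiers, 1 for each captured transcript) for 16971 genes in 5451 cells. The cells came from 2 libraries that form 1 group, and each cell carries the authors' name for 1 of 10 populations. Library 1 held 2260 cells and 11104066 UMIs, with a median of 4160.5 UMIs and 1780 genes per cell. Library 2 held 3191 cells and 19484171 UMIs, with a median of 5636 UMIs and 2118 genes per cell. Levels below are CPM (UMIs of a gene scaled to the UMIs of its population), as mean ± SD over the libraries. Fold changes are log2 values from 1 edgeR fit to the sums per library and population, with the library as a block (n = 2 libraries throughout). The ± beside a fold is a standard error derived from the test: the size of the fold over the square root of its quasi-likelihood F. The fit does not give it directly. A called gene has an adjusted p under 0.05.

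Smooth muscle cells (VSMC) were the most frequent population, with 40.9% ± 11.1 of cells (SD, n = 2), followed by the fibroblast populations Fibro 1 with 20.5% ± 4.57 and Fibro 2 with 11.3% ± 2.99. The 3 endothelial populations held 7.61% ± 1.51 (EC 1), 3.95% ± 2.08 (EC 2) and 1.69% ± 0.266 (EC 3) of cells. Mono 1 made up 8.11% ± 0.143, Macro 3.19% ± 1.06, Mono 2 1.97% ± 0.278 and Neuron 0.767% ± 0.334. Among endothelial cells alone, 58.2% ± 5.57 were EC 1, 28.7% ± 7.35 EC 2 and 13% ± 1.78 EC 3. The VSMC share was 48.8% in library 1 (exact Clopper-Pearson 95% interval 46.7 to 50.9) and 33.1% in library 2 (31.5 to 34.8). The EC 2 share was 2.48% in library 1 (1.88 to 3.21) and 5.42% in library 2 (4.66 to 6.26). These differences between the libraries exceed counting error, and with a single group no test between groups applies. When the cells were clustered again without the authors' names, 17 clusters were found and 99.5% of cells fell in a cluster of the same class.

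**Figure D1:**
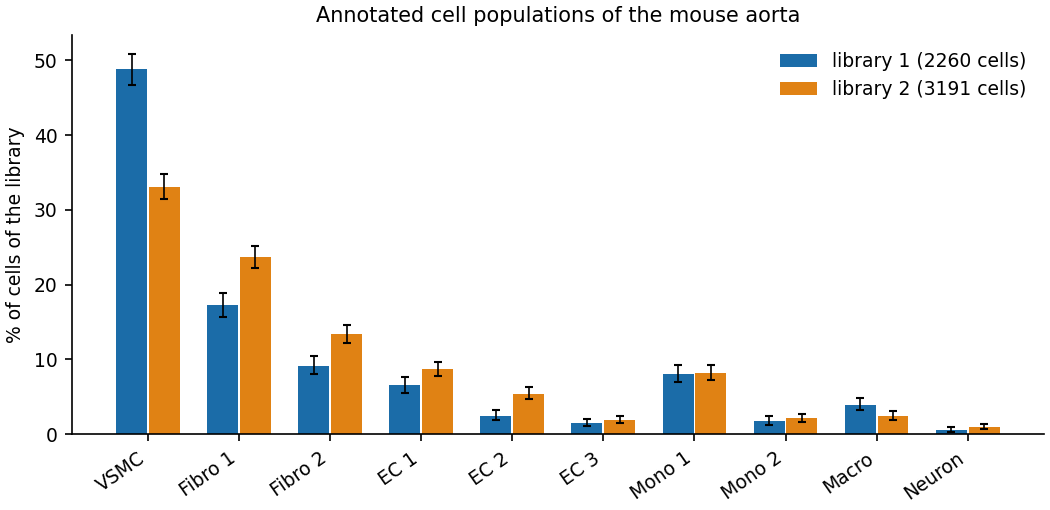
Share of cells in each annotated population (percent of the cells of the library), 1 bar for each library, with exact 95% intervals as error bars. VSMC took 48.8% of library 1 and 33.1% of library 2.

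The contents of the populations named Macro and Mono 1 went beyond their names. Of the 167 cells named Macro, 107 (64.1%) had at least 2 UMIs of T and NK cell genes such as Cd3g, and 49 (29.3%) had at least 2 UMIs of the B cell genes Cd79a, Cd79b and Ms4a1. In VSMC, which should lack both, the shares were 0.232% and 0.139%, at a median of 6025 UMIs per cell against 2730 in Macro. A single Macro cell (0.6%) had at least 2 UMIs of the macrophage genes Cd68, Adgre1 and Csf1r, a share close to the 0.417% of VSMC. The complement gene C1qa stood at 7649 ± 492 in Mono 1, 536 ± 211 in Mono 2 and 37.6 ± 11.8 in Macro, and the mannose receptor Mrc1 at 1563 ± 158, 205 ± 15.6 and 1.77 ± 2.5.

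The first set of comparisons asks what each major class expresses that the others do not: each class, as the mean of its populations, was compared with the mean of the other 3 classes. The cadherin Cdh5, which holds endothelial junctions together, was higher by 6.39 ± 0.12 and the adhesion molecule Pecam1 by 4.51 ± 0.13 on the log2 scale, in both libraries (adjusted p = 2.72e-26 and 1.76e-23). The transcription factor Sox18 (7.79 ± 0.31), the Notch ligand Dll4 (7.43 ± 0.45), the sialomucin Emcn (7.24 ± 0.14) and the tight junction gene Cldn5 (6.75 ± 0.18) were among the largest. Of 10488 genes tested, 3469 were called, 1825 higher and 1644 lower, a balance that turned without a filter on low counts (1756 and 1921). All 15 pan-endothelial markers were higher (15 adjusted over the list alone). Of 16 angiogenesis genes 13 were higher, and of 15 flow and vasodilator genes 10 were higher, 3 lower and 2 not past the threshold (14 and 11 higher adjusted over the list alone). Of 12 interferon response genes 10 were higher, among them Isg15 (2.15 ± 0.32) and Bst2 (1.85 ± 0.12), with the same 10 adjusted over the list alone. Fatty acid handling genes were higher in 16 and lower in 3 of 24 (17 and 3 adjusted over the list alone), led by Fabp4 (3.86 ± 0.26) and Cd36 (3.06 ± 0.15).

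Smooth muscle differed from the other classes in its contractile apparatus. The actin gene Acta2 was higher by 4.82 ± 0.12, the myosin heavy chain Myh11 by 4.67 ± 0.12 and the actin-binding gene Tagln by 5.11 ± 0.14 (adjusted p = 5.96e-25, 5.96e-25 and 7.01e-24), in both libraries. Outside the contractile genes, the Wnt pathway genes Wnt16 (6.19 ± 0.43) and Wif1 (6.08 ± 0.34) and the growth factor binding protein Igfbp2 (5.81 ± 0.22) were among the largest. In all, 5171 genes were called, 3008 higher and 2163 lower, and with DESeq2 the balance turned, with 45.3% of its calls higher against 58.2%. All 14 contractile genes tested were higher. Of 17 genes of heritable thoracic aortic disease, 14 were higher and 1 lower, and of 43 matrix genes 32 were higher and 6 lower, with the elastin gene Eln at 2.26 ± 0.16 and the matrix Gla protein gene Mgp at 1.99 ± 0.17. Adjusted over the list alone these 3 lists gave 14, 14 and 32 higher genes. Interferon response genes were lower in 11 of 12 and MHC class II genes in 7 of 8 (11 and 7 adjusted over the list alone).

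In fibroblasts all 15 fibroblast markers and most matrix genes were higher. Pdgfra, the receptor for platelet-derived growth factor, was higher by 5.93 ± 0.13 and the lectin Clec3b by 5.49 ± 0.14, in both libraries (adjusted p = 3.32e-25 and 3.43e-25). The transcription factor Twist2 (6.02 ± 0.29), the secreted genes Cilp (5.86 ± 0.19) and Srpx (5.84 ± 0.17) and the membrane gene Ms4a4d (6.76 ± 0.18) were among the largest. Of 4921 called genes 2898 were higher and 2023 lower. Of 15 fibroblast markers 15 were higher, and of 43 matrix genes 38 were higher, 3 lower and 2 not past the threshold (15 and 38 higher adjusted over the list alone). Fbln1 stood at 5.04 ± 0.12 and Col1a1 at 4.18 ± 0.12, and Eln at only 0.64 ± 0.15. Of 10 genes of modulated smooth muscle 9 were higher in fibroblasts (9 adjusted over the list alone), and 3 were higher and 5 lower in smooth muscle.

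The immune class (Mono 1, Mono 2 and Macro) was higher in all 8 MHC class II genes tested. The leukocyte phosphatase Ptprc was higher by 7.85 ± 0.17, the chemokine receptor Ccr2 by 9.35 ± 0.32 and the MHC class II chaperone Cd74 by 6.97 ± 0.19, in both libraries (adjusted p = 3.91e-26, 6.47e-20 and 6.98e-24). The guanine exchange factor Dock2 (8.38 ± 0.27) and the innate receptor partner Ly86 (8.23 ± 0.30) were among the largest. Of 5270 called genes 2364 were higher and 2906 lower, a balance that turned with DESeq2 (2766 and 2733). Of 8 MHC class II genes 8 were higher, 13 of 16 macrophage genes were too, and all 43 matrix genes were lower (8, 13 and 43 adjusted over the list alone). Cell cycle genes were higher in 13 of 14 (13 adjusted over the list alone), among them Top2a (6.40 ± 0.45). Immediate early genes, which respond to dissociation, were higher in 13 of 17 and lower in 1 (13 and 1 adjusted over the list alone), with Fos at 0.93 ± 0.12. Because the class mean gives Macro the same weight as the others, Cd68 stood at 4.83 ± 0.61 although it was near background in Macro.

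The second set of comparisons asks how the endothelial populations differ from each other. EC 1 and EC 2 were both endothelial by Cdh5, at 389 ± 24 and 1019 ± 109.7, and 13 of 28 gene lists were called between them, or 2 with an estimated correlation. EC 1 held the leukocyte adhesion molecule Vcam1 at 1167 ± 292 against 44.3 ± 12.7 in EC 2 (log2 fold change of EC 1 against EC 2 4.89 ± 0.33, adjusted p = 3.82e-13). EC 2 held the fatty acid transporter Cd36 at 3578 ± 883 against 30.6 ± 1.23 in EC 1 (-6.80 ± 0.27, adjusted p = 1.13e-18). The fatty acid binding protein Fabp4 reached 33310 ± 3331 in EC 2 and 249 ± 100 in EC 1 (-7.04 ± 0.57, adjusted p = 1.66e-11). All of these held in both libraries, and 2130 of 10488 genes were called, 1162 higher in EC 1 and 968 higher in EC 2 (945 and 1008 with DESeq2).

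**Figure D2:**
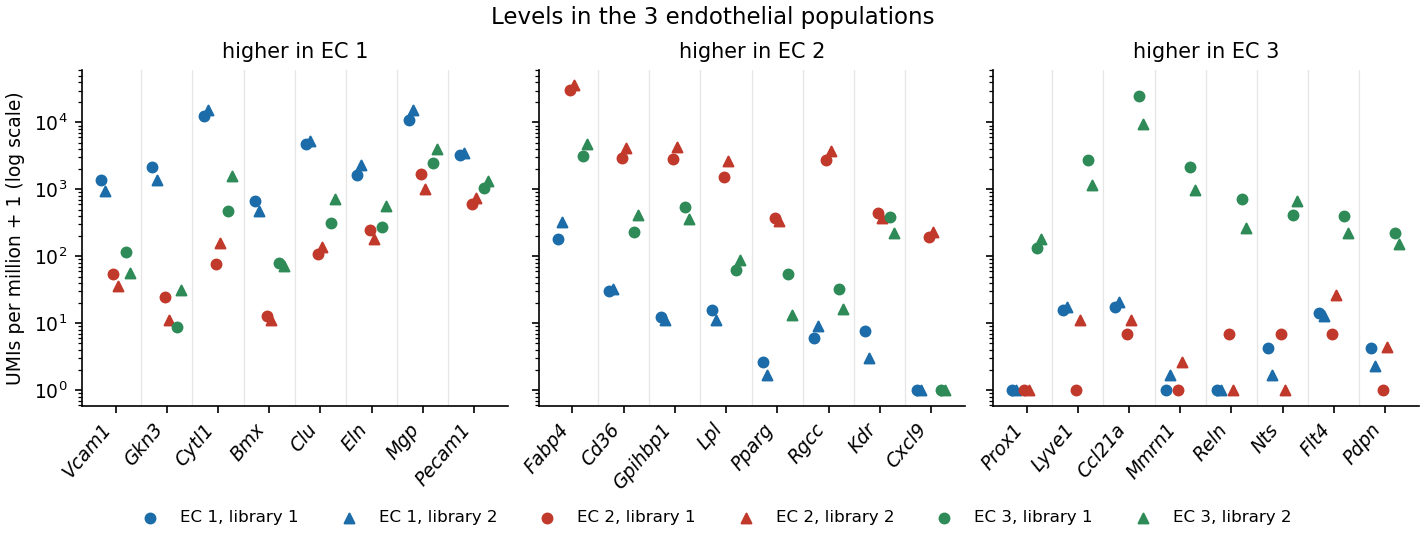
Levels of 24 genes in the 3 endothelial populations (CPM plus 1, log axis), 1 point for each library. Circles are library 1 and triangles library 2, and each panel holds genes that are highest in 1 population.

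Of 24 fatty acid and lipoprotein handling genes, 15 were lower in EC 1, 1 was higher and 8 were not past the threshold (16 and 1 adjusted over the list alone). This list and the matrix list follow the known theme of the study and are not independent evidence. Gpihbp1, which carries lipoprotein lipase across the capillary wall, was lower in EC 1, at -8.31 ± 0.43, and the lipase gene Lpl itself at -7.43 ± 0.30. Their regulators Tcf15 (-7.44 ± 0.35) and Meox2 (-6.33 ± 0.43) were lower too, and Pparg, with 2 UMIs in EC 1, was higher in EC 2 by 359-fold (95% counting interval 98.4 to 2980). The exception was Apoe, the apolipoprotein E gene, higher in EC 1 by 2.19 ± 0.20. As a set the list was lower in EC 1 (camera adjusted p = 1.9e-14, and 0.0285 with an estimated correlation), with a median log2 of -3.50. Adipocyte markers moved with it (camera adjusted p = 0.00037, and 0.064 with an estimated correlation), and adipocytes also express Fabp4, Cd36, Lpl and Pparg. Capillary markers moved with them, lower in 8 of 9 and higher in 1 (the same counts adjusted over the list alone), with the cell cycle regulator Rgcc at -8.77 ± 0.32 and the carbonic anhydrase Car4 at -8.40 ± 0.34. Their camera adjusted p was 9.85e-15, or 0.0285 with an estimated correlation, and their median log2 was -8.04, or -6.80 with genes absent from 1 population at their bound. The exception was Plvap, a gene of fenestrated endothelium (1.44 ± 0.37), whose fold was 0.21 in library 1 and 2.33 in library 2.

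Of 16 angiogenesis and VEGF response genes 9 were higher in EC 2, a part of which, Kdr and Aplnr among them, the capillary list also holds. The VEGF receptor Kdr was lower in EC 1, at -6.70 ± 0.34, and its homologue Flt1 at -3.91 ± 0.20, and the apelin receptor gene Aplnr, with no UMI in EC 1, was at least 75.2-fold higher in EC 2 (against 3 counts over the population). In the list 9 were lower in EC 1, 3 higher and 4 not past the threshold (10 and 3 adjusted over the list alone; camera adjusted p = 9.13e-06, and 0.0552 with an estimated correlation). Interferon genes fell the same way in 6 of 12 and rose in none (7 and 1 adjusted over the list alone). The antiviral gene Rsad2 stood at -6.37 ± 0.32, and the interferon-induced chemokine Cxcl9, with no UMI in EC 1, was at least 157-fold higher in EC 2. Their camera adjusted p was 0.00142, and 0.346 with an estimated correlation. Immediate early genes were lower in EC 1 in 9 of 17 (9 adjusted over the list alone), with Fos at -1.73 ± 0.25 and Btg2 at -1.87 ± 0.34 (camera adjusted p = 0.00309, and 0.512 with an estimated correlation). Among the largest folds towards EC 2 were genes without a UMI in EC 1, such as the cytoskeletal gene Ablim3 (at least 192-fold) and the nucleoside transporter Slc28a2 (at least 104-fold).

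Part of the arterial, matrix and adhesion genes were higher in EC 1. The tyrosine kinase Bmx was higher by 5.75 ± 0.28 and the connexin Gja4 by 3.37 ± 0.27, and 10 of 18 arterial markers were higher, 5 lower and 3 not past the threshold (10 and 7 adjusted over the list alone). As a set they were higher in EC 1 (camera adjusted p = 0.0214, and 0.16 with an estimated correlation). Among matrix genes, Eln was higher by 3.44 ± 0.30, Mgp by 3.36 ± 0.31 and the thrombospondin Thbs1 by 5.01 ± 0.34, while the basement membrane-associated gene Sparcl1 was lower, at -4.21 ± 0.23. In the whole list of 43, 17 were higher, 6 lower and 20 not past the threshold (17 and 9 adjusted over the list alone; camera adjusted p = 0.0207, and 0.418 with an estimated correlation). Adhesion genes were higher in 9 and lower in 4 of 19 (11 and 4 adjusted over the list alone), with Pecam1 at 2.44 ± 0.22 and P-selectin (Selp) at 4.05 ± 0.40 (6.76 in library 1 and 3.50 in library 2). Their camera adjusted p was 0.00669, and 0.223 with an estimated correlation.

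Flow and vasodilator genes did not move as 1 block. The angiotensin-converting enzyme Ace was higher in EC 1 by 4.39 ± 0.29 and Cyp1b1 by 4.44 ± 0.40 (2.90 and 5.02 in the libraries), whereas the endothelin receptor Ednrb, with 2 UMIs in EC 1, was higher in EC 2 by 258-fold (95% counting interval 70.6 to 2150). Of 15 genes 6 were higher, 2 lower and 7 not past the threshold (7 and 2 adjusted over the list alone). The flow-induced factor Klf2 was among the last, at 0.32 (adjusted p = 0.344). The set was higher in EC 1 (camera adjusted p = 0.00269, and 0.0887 with an estimated correlation). The von Willebrand factor gene Vwf, which the venous list and the pan-endothelial list share, was higher in EC 1 by 4.74 ± 0.27, and Nrp2, with 2 UMIs in EC 1, was higher in EC 2 by 227-fold (95% counting interval 61.8 to 1890). The venous list had a median log2 of 0.88 and a mean of -0.21, and was not called (camera adjusted p = 0.465). Among the largest folds towards EC 1 were genes without a UMI in EC 2, such as the hedgehog ligand Dhh (at least 26.7-fold) and the adrenergic receptor Adra2a (at least 21.3-fold).

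MHC class II genes were higher in EC 1, and macrophage genes were not. Cd74 stood at 557 ± 210.0 in EC 1 and 88.9 ± 16.6 in EC 2 (2.88 ± 0.37, adjusted p = 2.42e-07), against 77.8 ± 27.7 in VSMC. H2-Eb1 followed at 3.30 ± 0.47 and H2-Aa at 2.71 ± 0.40, and of 8 genes 6 were higher in EC 1 and none lower, with the same counts adjusted over the list alone. The size of the difference depended on the library, since H2-Ab1 stood at 0.64 in library 1 and 3.56 in library 2, and H2-Eb1 at 1.26 and 4.41. The 10% of EC 1 cells with most MHC class II UMIs held 53.2% of them, and the median cell held 1 in library 1 and 3 in library 2, against 1 in VSMC of each library. The set was called (camera adjusted p = 0.00108, and 0.406 with an estimated correlation). None of 16 macrophage genes was called, either over all genes or adjusted over the list alone, and C1qa stood at 0.43 ± 0.51 (adjusted p = 0.653).

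Genes of other cell types also separated EC 2 from EC 1. Of 5 adipocyte genes tested, 4 were lower in EC 1 (4 adjusted over the list alone), with the gluconeogenic enzyme Pck1 at -4.20 ± 0.49, the carbonic anhydrase Car3 at -3.62 ± 0.39 (-5.79 and -3.13 in the libraries) and the lipid droplet gene Cidec at -3.23 ± 0.57 (camera adjusted p = 0.00037, and 0.064 with an estimated correlation). Of 9 pericyte genes 6 were lower in EC 1 (8 adjusted over the list alone), with Rgs5 at -3.73 ± 0.29 and Notch3, which had no UMI in EC 1, at least 34.8-fold higher in EC 2. Their camera adjusted p was 5e-06, and 0.169 with an estimated correlation. The pericyte UMIs of EC 2 lay in few cells, 24 of 229 holding 85.7% of them. Without endothelial cells rich in pericyte or haemoglobin UMIs the pericyte list and Notch3 were no longer called. The cells left out were picked by UMIs of this same list, so the loss was largely set by the selection. The smooth muscle gene Acta2 was not called (-0.15, adjusted p = 0.723), and its fold was -0.57 in library 1 and 0.34 in library 2.

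EC 3 as a whole carried the lymphatic markers. When all cells were clustered again, 92 of its 94 cells lay in a single cluster. On 1 part of the split UMIs they fell into separate clusters with 61 and 32 of its cells, which were joined as EC 3. Whether both carry the lymphatic genes, and the other genes of EC 3 given below, was not tested. The lymphatic master regulator Prox1 reached 155 ± 33.1 in EC 3 and had no UMI in EC 1 or EC 2, so it was at least 116-fold higher than in EC 1 and at least 42.2-fold higher than in EC 2. With DESeq2 Prox1 missed the threshold in both comparisons. The hyaluronan receptor Lyve1 was lower in EC 1 than in EC 3, at -6.55 ± 0.32 (adjusted p = 6.67e-16), and the chemokine Ccl21a at -9.42 ± 0.58 (adjusted p = 1.03e-13). Ccl21a stood at 17160 ± 10690 in EC 3, and at -10.21 and -8.65 in the fold change of each library. Between EC 1 and EC 3 1218 genes were called, 626 higher in EC 1 and 592 higher in EC 3, a balance that turned with RLE size factors (553 and 620), DESeq2 (490 and 609) and no library term (439 and 520). All but 1 of 13 lymphatic markers were lower in EC 1 (12 called, 12 adjusted over the list alone), and the exception, Itga9, stood at -0.18 ± 0.21 (adjusted p = 0.729). The set had a camera adjusted p of 3.3e-28, or 0.00382 with an estimated correlation. Beyond the list, the acute-phase gene Lrg1 (-8.03 ± 0.26) and Lcn2 (-7.75 ± 0.81) were lower in EC 1, and the tight junction gene Cldn11, with no UMI in EC 1, was at least 82-fold higher in EC 3. Cldn11 was not called with DESeq2.

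Against EC 3, most arterial genes and part of the adhesion and matrix genes were higher in EC 1. Vcam1 was higher by 4.08 ± 0.34 (adjusted p = 8.18e-11), Eln by 2.35 ± 0.28 and Mgp by 2.21 ± 0.29 (adjusted p = 2.2e-07 and 1.03e-06). The alcohol dehydrogenase Adh7, with no UMI in EC 3, was at least 77-fold higher in EC 1, the cardiac and neural factor Isl1 at least 11.4-fold and the connexin Gja5 at least 6.68-fold. Arterial markers were higher in 12 of 18 and lower in 1 (13 and 1 adjusted over the list alone), as a set with a camera adjusted p of 1.29e-08, or 0.0313 with an estimated correlation. Matrix genes were higher in 14 and lower in 4 of 43 (15 and 4 adjusted over the list alone; camera adjusted p = 0.00213, and 0.202 with an estimated correlation). Adhesion genes were higher in 7 and lower in 2 of 19, and flow genes in 7 and 1 of 15, among them the prostacyclin synthase Ptgis (3.29 ± 0.31). Adjusted over the list alone these were 9 and 2, and 7 and 2. The camera adjusted p was 0.000946 for adhesion and 0.00142 for flow, and 0.0887 and 0.064 with an estimated correlation. Genes of lipid handling were lower in EC 1 in 12 of 24 and higher in 2, with the same counts adjusted over the list alone, among them Fabp4 (-3.84 ± 0.50) and Cd36 (-3.30 ± 0.29). Their camera adjusted p was 2.66e-05, and 0.0612 with an estimated correlation. The capillary and angiogenesis lists were lower and the modulated smooth muscle and erythrocyte lists higher in EC 1, with adjusted p of 9.56e-09, 0.0164, 0.0154 and 0.0154. With an estimated correlation these became 0.0552, 0.169, 0.0887 and 0.502. In EC 1, 10 cells held 77.4% of the haemoglobin UMIs, and without endothelial cells rich in pericyte or haemoglobin UMIs the erythrocyte list was not called. That loss was largely set by the selection, which used the same genes. The MHC class II list was not called between EC 1 and EC 3 (median log2 0.23, camera adjusted p = 0.944), and 1 of its genes, Cd74 (0.95 ± 0.32, adjusted p = 0.052), was higher in EC 1 adjusted over the list alone. The fold of Cd74 was 0.06 in library 1 and 1.51 in library 2.

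EC 2 and EC 3 shared part of the lipid genes, but EC 2 was higher. Fabp4 stood at 33310 ± 3331 in EC 2 and 3932 ± 1082 in EC 3 (3.20 ± 0.47, adjusted p = 7.04e-06), and Gpihbp1 at 3553 ± 1024 and 456 ± 135 (3.07 ± 0.32, adjusted p = 1.14e-08). Lpl was higher in EC 2 by 4.87 ± 0.29, the scavenger receptor Scarb1 by 4.04 ± 0.38 (7.20 and 3.65 in the libraries) and Pparg by 3.86 ± 0.38. Of 24 lipid genes 15 were higher in EC 2 and 0 lower (16 and 1 adjusted over the list alone; camera adjusted p = 2.01e-13, and 0.0113 with an estimated correlation). Capillary genes were higher in 7 of 9 and lower in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 1.06e-10, and 0.0332 with an estimated correlation), with Rgcc at 7.46 ± 0.35 and, on the other side, Plvap at -3.91 ± 0.32 (-2.0 and -5.10 in the libraries). All 13 lymphatic markers were lower in EC 2, among them Ccl21a (-10.54 ± 0.69) and Lyve1 (-7.68 ± 0.42; -10.70 and -6.62 in the libraries), and all of them remained so adjusted over the list alone (camera adjusted p = 4.63e-29, and 0.00519 with an estimated correlation). Venous markers were lower in EC 2 in 6 of 10 (7 adjusted over the list alone; camera adjusted p = 3.91e-08, and 0.0182 with an estimated correlation), with Vwf at -4.66 ± 0.29 and the venous factor Nr2f2 at -2.73 ± 0.23. In all, 1226 genes were called, 579 higher in EC 2 and 647 higher in EC 3. This balance turned after thinning (349 and 300), with split UMIs (408 and 381) and without a filter (651 and 649).

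MHC class II and immediate early genes were called between EC 2 and EC 3 in the direction in which they were called against EC 1. Both comparisons use the same EC 2 cells, so they are not independent. MHC class II genes were lower in EC 2 in 6 of 8, with H2-Aa at -2.71 ± 0.44, immediate early genes were higher in 8 of 17, and interferon genes in 2 of 12, lower in 1. The MHC class II UMIs of EC 3 lay in part of its cells: the 10% of cells with most of them held 66.1% (78.4% in library 1), and the median cell held 1, as in VSMC. Adjusted over the list alone the counts were 6, 11 and 5. The camera adjusted p of the 3 lists was 2.87e-05, 4.38e-05 and 0.0162, and 0.223, 0.346 and 0.538 with an estimated correlation. The angiogenesis list was higher in EC 2 (camera adjusted p = 0.00804, and 0.173 with an estimated correlation), with Adgrl4 at 3.02 ± 0.30 and Flt1 at 2.12 ± 0.21. The lists of pericyte, adipocyte, fibroblast, contractile and erythrocyte genes were higher in EC 2 as well, with adjusted p of 2.51e-05, 3.24e-05, 0.00213, 0.00269 and 0.00862. With an estimated correlation these were 0.202, 0.0887, 0.485, 0.498 and 0.485. Of these only the pericyte and adipocyte lists had also been called against EC 1. The median EC 2 cell held 5 contractile UMIs and the median EC 3 cell 7, at medians of 2658 and 4139 UMIs of all genes. Whether background at a lower depth gives the higher share in EC 2 was not tested. With doublets left out the contractile and fibroblast lists were no longer called, and without endothelial cells rich in pericyte or haemoglobin UMIs the fibroblast, pericyte and erythrocyte lists were not. For the pericyte and erythrocyte lists this loss was largely set by the selection, which used the same genes. The haemoglobin gene Hba-a2 stood at 3.74 ± 0.76, but 2 cells of EC 2 held 87.9% of the haemoglobin UMIs of that population. The fold of Hbb-bs, 2.51 over both libraries, was 0.21 in library 1 and 3.4 in library 2.

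**Figure D3:**
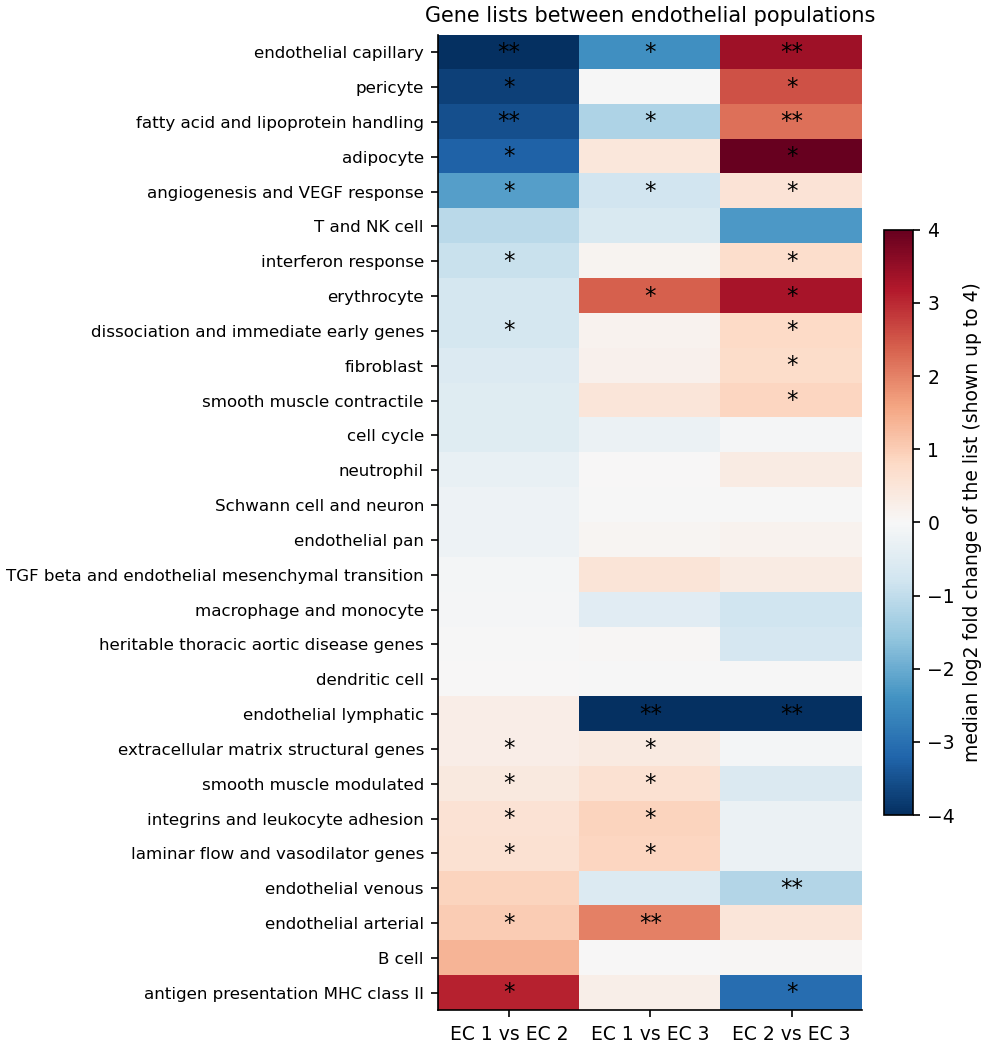
Median log2 fold change of each gene list in the 3 comparisons of endothelial populations (colour, drawn up to 4 in size). A star marks lists with a camera adjusted p under 0.05, and 2 stars those that stay so with an estimated correlation.

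In the 3 comparisons 13, 10 and 13 of 28 lists were called, and with an estimated correlation 2, 2 and 4. Several lists had a median that differed in sign from the mean or the test. Between EC 1 and EC 2 the genes of TGF beta and endothelial-mesenchymal transition had a median log2 of -0.07 and a mean of 0.25, and the aortic disease genes -0.02 and 0.57. Neither was called by camera in the 3 comparisons, but with doublets left out the aortic disease list was called between EC 2 and EC 3, as was the matrix list. The pan-endothelial list had a median of 0.07 and a mean of -0.55 between EC 1 and EC 3, and the B cell list a median of 1.36 between EC 1 and EC 2 where camera pointed lower (adjusted p = 0.561). The modulated smooth muscle list, which holds Vcam1 and Mgp, was higher in EC 1 than in EC 2 (camera adjusted p = 0.025, and 0.146 with an estimated correlation). No cell cycle gene was called between endothelial populations with edgeR. The populations were defined from the same expression values, so the p-values do not test whether they exist and may be too small. They also depend on the depth of each population and do not measure how far apart the populations lie.

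The fold changes of single genes differed between the libraries. Across 10488 genes the log2 fold changes of the libraries correlated with Pearson's r of 0.656 for EC 1 against EC 2, 0.513 for EC 1 against EC 3 and 0.464 for EC 2 against EC 3 (Spearman's rho 0.506, 0.364 and 0.362). Genes are not independent replicates, so these values carry no p. Among genes with at least 50 UMIs in the populations compared, r was 0.799, 0.693 and 0.779, and with cells thinned to equal UMIs 0.651, 0.454 and 0.447. Of the called genes, 98.8%, 99.2% and 98.1% had the same sign in library 1 alone, and 99.9%, 99.9% and 99.9% in library 2 alone. These genes were called from a fit to both libraries, so their agreement in sign was in part set by the call.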

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

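The tests of other-cell transcripts below were all chosen only after the results they measure were seen, and a part of them runs on cells picked by the same transcripts. The small population named Neuron enters no comparison, and a signal in it stood out from the level in VSMC. It held 3222 UMIs of the airway secretory gene Scgb1a1, all in 1 cell of library 1, which also carried 1232 UMIs of Bpifa1 and 321 of Scgb3a2. Scgb1a1 had 54 UMIs in the 2159 VSMC cells, at most 2 in a cell. No explanation of this signal was tested.

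Adipocyte list genes were higher in EC 2 than in EC 1, and the protocol removed perivascular fat before dissociation per the labels. As a set they were not called with an estimated correlation (camera adjusted p = 0.064) or without the library term. Adipocyte transcripts were present in every large population of library 2 (a UMI in 60.4% of VSMC cells and 85.0% of EC 2 cells, against 5.44% and 42.9% in library 1, at medians of 6025 and 2658 UMIs over both libraries). The 4 called genes Pck1, Car3, Cidec and Cfd were compared with the other populations of the same library. EC 2 held 3.61 times their UMIs per cell (95% interval 3.31 to 3.93), 16.9 times in library 1 and 3.32 in library 2. The interval takes UMIs as independent. These genes were picked because they were called higher in EC 2, so the rise in part restates that call. Cfd, with 205 of the 526 UMIs, rose only 1.95 times (1.7 to 2.24). Over the whole fixed list EC 2 held 1 and 2.92 UMIs per cell in libraries 1 and 2. VSMC held 0.0571 and 1.01, and Neuron, the highest other population in library 2, 0 and 2.25. The 4 called genes gave 526 of the 562 list UMIs of EC 2, so the whole list largely restates their rise. This argues against free RNA as the whole cause only for these 4 genes, which were picked by their call. For the other 5 genes free RNA stays open, since in library 2 they rose 1.35 times (0.925 to 1.91). Whether adipocytes joined to EC 2 cells remains open: the other 5 list genes together rose 1.5 times (1.05 to 2.07; 10.5 times on 4 UMIs in library 1 and 1.35 in library 2), but Plin1 among them rose 6.80 times (3.4 to 12.2) on 11 UMIs, while Retn stood at 1.02 and Adipoq at 1.30. For the lipid list genes that adipocytes express, this was not tested. UMIs of Fabp4 and Cd36 were in all 209 EC 2 cells with under 5 Rgs5 UMIs, at 112 and 12.7 per cell, and in all 20 others. Adipoq had 8 UMIs in the whole population. Adipocytes joined to only a part of the EC 2 cells could thus not be the whole source of Fabp4 and Cd36. Lpl and Pparg were not counted by cell. Expression by the cells themselves may also contribute, and no biological explanation was tested.

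Pericyte list genes were higher in EC 2 than in EC 1 (6 of 9 called) and EC 3 (5 of 9 called). As a set they were not called with an estimated correlation (camera adjusted p = 0.169 and 0.202). Free RNA in every droplet is argued against, since the mean EC 2 cell held 3.21 of these UMIs and the median cell 0. The 20 EC 2 cells with at least 5 UMIs of Rgs5 held 52.5 times the other pericyte UMIs of the rest (10.6 against 0.201 per cell), although their depth was only 2.39 times as high (medians 6151.5 and 2576 UMIs), and all 20 had Cdh5 UMIs. A candidate explanation is a small number of endothelial cells joined to pericytes. The list is not particular to pericytes here: it reached 10.3 UMIs per cell in VSMC and 5.63 in Fibro 1. Of its 9 genes 7 were higher in smooth muscle than in the other classes and 1 was lower. This count alone thus cannot tell pericytes from such cells as the partner. Of the 20 cells 2 were called doublets, against 6 of the 209 others. So few calls do not decide, and single cells that express both sets of genes stay open. No biological explanation was tested.

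Haemoglobin genes were higher in EC 2 than in EC 3, by 14.1 times as a share of UMIs in library 2 and 1.06 times in library 1. Without endothelial cells of at least 100 haemoglobin UMIs (2 in EC 2, none in EC 3) the ratio was at most 1.19. The median EC 2 cell held 10 haemoglobin UMIs in library 1 and 6 in library 2, and the median EC 3 cell 11 and 9. The difference may thus rest on 2 cells, although these cells were picked by the haemoglobin they hold. Red cells were lysed per the labels, and no biological explanation was tested.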

How the results depend on the processing

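The alternative that leaves out endothelial cells with at least 5 UMIs of the pericyte list or 100 of the erythrocyte list (14, 26 and 1 cells of EC 1, EC 2 and EC 3) was chosen after seeing the data, as were all comparisons of fibroblast and monocyte populations. The counts of called genes stayed within 1.5 times under every alternative except those named here. With cells thinned to 1300 UMIs, 1262 genes were called between EC 1 and EC 2, 667 between EC 1 and EC 3 and 649 between EC 2 and EC 3, and 1813, 2791, 2522 and 2857 for the endothelial, smooth muscle, fibroblast and immune classes. Thinning left no cell out and lowers the counts by construction. With UMIs split at random into 2 equal parts and clusters made on 1 of them, 789 genes were called between EC 2 and EC 3 on the other, which holds fewer counts by construction. Between Fibro 1 and Fibro 2 the count was 939 without the library term, 702 after thinning and 1078 with DESeq2, and between Mono 1 and Mono 2 it was 612 after thinning and 1183 with the split UMIs. No clusters were remade for Mono 1 and Mono 2, so the split there only lowers the counts. The balance of higher and lower genes was less stable. It turned between EC 1 and EC 2 with RLE size factors (1057 and 1067) and DESeq2, and between EC 1 and EC 3 with RLE size factors, DESeq2 and no library term, with 667 and 667 when only these populations were fitted. Between EC 2 and EC 3 it turned without a filter (651 and 649), after thinning (349 and 300) and with the split UMIs (408 and 381), with 506 and 506 when only these populations were fitted. It also turned without a filter for the endothelial class (1756 and 1921), with DESeq2 for the smooth muscle (2281 and 2756) and immune (2766 and 2733) classes, after thinning between Fibro 1 and Fibro 2 (323 and 379), and with RLE size factors (852 and 939) and DESeq2 (676 and 854) between Mono 1 and Mono 2. No gene called both in the report and under an alternative changed sign.

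The gene lists depended most on the correlation between genes: with an estimated correlation 2, 2 and 4 lists were called against 13, 10 and 13, and with fry 18, 12 and 11. Without the cells with other transcripts, 12, 9 and 10 lists and 2028, 1228 and 1246 genes were called: the pericyte list was lost between EC 1 and EC 2, the erythrocyte list between EC 1 and EC 3, and the fibroblast, pericyte and erythrocyte lists between EC 2 and EC 3. These cells were picked by UMIs of the pericyte and erythrocyte lists, so the losses of these lists and of their genes were largely set by the selection. With doublets left out, the contractile and fibroblast lists were lost and the matrix and aortic disease lists gained between EC 2 and EC 3. The split UMIs lost the arterial list between EC 1 and EC 2 and the contractile list between EC 2 and EC 3, no filter lost the erythrocyte list in both comparisons with EC 3, and no library term lost the adipocyte list between EC 1 and EC 2 and gained the venous list between EC 1 and EC 3. Without the cells with other transcripts Notch3 missed the threshold between EC 1 and EC 2 (-4.26), as did Hba-a2 (0.56) and Hbb-bs (0.29) between EC 2 and EC 3. With DESeq2 the same was true of Plvap between EC 1 and EC 2 (1.02), Cldn11 (-9.04) and Prox1 (-9.58) between EC 1 and EC 3, Prox1 between EC 2 and EC 3 (-8.06) and Mmp12 between Mono 1 and Mono 2 (-4.51). Acta2 between EC 1 and EC 2, not called at -0.15, was called at 0.54 in the opposite direction without the 10% of cells with fewest and the 10% with most UMIs. Cd74 between EC 1 and EC 3, not called at 0.95, was called under 7 alternatives, with folds from 0.83 (only the populations compared) to 2.31 (after thinning). The cause of these changes was not tested. Folds of single libraries carry a prior count of 2 and those with equal weight of cells an added 5 CPM, unlike the main fit. These additions shrink folds of genes near 0 in 1 population by construction, so part of the following moves may come from them. Of 132 folds of named genes, 50 moved by over 1 (log2) in library 1 alone, 31 in library 2 alone and 45 with equal weight of cells, all with the same sign where called. For the genes with the largest folds, the naming rule required the same sign in each library, so that agreement was fixed in advance.

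Shares of populations were counted again without doublets and without the cells with fewest UMIs, and shares of classes with own clusters. These shares moved by less than the SD of the libraries, except Mono 1, at 7.95% without doublets. Each library alone cannot test this, since the libraries themselves set the SD. The SD is wide where the libraries differed, as for VSMC (48.8% in library 1 and 33.1% in library 2) and EC 2 (2.48% and 5.42%). Within that SD, leaving out the cells with fewest UMIs lowered EC 2 from 3.95% to 3.10% (229 to 161 cells). The same step lowered Neuron from 0.767% to 0.559%. The correlation of the libraries rose to 0.799, 0.693 and 0.779 among genes with at least 50 UMIs, and was 0.651, 0.454 and 0.447 with cells thinned to equal UMIs.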

Other observations

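The comparisons of the fibroblast and of the monocyte populations were chosen after the data were seen, and so were the genes named here. The collagen-binding gene Fmod was higher in Fibro 1 by 5.32 ± 0.21 (adjusted p = 2.95e-18), the matricellular gene Smoc1 by 4.21 ± 0.19 and the retinol carrier Rbp4 by 3.87 ± 0.18. Fibro 2 held the chemokines Cxcl13 (-7.52 ± 0.34) and Ccl11 (-4.72 ± 0.19), the peptidase Dpp4 (-5.69 ± 0.30) and the protein C receptor Procr (-5.54 ± 0.21). Of 1626 called genes 871 were higher in Fibro 1 and 755 in Fibro 2 (323 and 379 after thinning). Matrix genes were higher in Fibro 1 in 18 of 43 and lower in 8, TGF beta genes in 13 and 2 of 26, and aortic disease genes in 8 and 3 of 17. Flow genes were lower in 7 of 15 and interferon genes in 4 of 12, with none higher. Pericyte genes moved with them, higher in Fibro 1 in 6 of 9 and lower in none, as did contractile genes, higher in 7 and lower in 1 of 14. The lists were counted and not tested as sets.

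Mono 1 and Mono 2 divided the myeloid genes. The scavenger receptor Stab1 was higher in Mono 1 by 5.82 ± 0.32, the platelet factor gene Pf4 by 5.95 ± 0.31 and the hyaluronan receptor Lyve1 by 7.51 ± 0.42 (adjusted p = 1.37e-14), and the lectin Cd209f, with no UMI in Mono 2, was at least 141-fold higher. Mono 2 held Ccr2 (-4.20 ± 0.22), the ribonuclease Ear2 (-6.99 ± 0.27), the protease Mmp12 (-4.48 ± 0.39) and Plac8 (-4.88 ± 0.41). Of 1797 called genes 945 were higher in Mono 1 and 852 in Mono 2 (676 and 854 with DESeq2). Of 16 macrophage and monocyte genes 12 were higher in Mono 1 and 3 lower, while 7 of 8 MHC class II genes and 7 of 9 dendritic cell genes were lower and none higher. Of 5 neutrophil genes 4 were lower and 1 higher, with S100a8 at -7.45 ± 0.76 (-7.59 in library 1 and -0.77 in library 2).

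In the population named Macro, 3191 UMIs of the immunoglobulin joining chain Jchain lay in 1 cell.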
